A study of Aplysia californica with 8 samples.

How the data were processed

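Gene expression was measured in pleural ganglia of Aplysia californica on 8 two-colour Agilent arrays, each with RNA of the trained side in 1 dye and of the untrained side of the same 2 animals in the other. Per the labels, 300 ng of total RNA was amplified and labelled for each channel. The scanner files hold spot and background intensity of the green (Cy3) and red (Cy5) channel in arbitrary units, which per the file headers came from Feature Extraction 11.5.1.1. They also hold processed intensity values, which per the file headers were background-subtracted and dye-normalised by linear and lowess factors. The deposited log ratio of the scanner files is log10 of Cy5 over Cy3, and other deposited columns are flags of 0 or 1 for signal well above background, saturation and outliers. The deposited value table holds log2 of Cy5 over Cy3 after loess in limma by the authors, with array medians from 0.0051 to 0.0091, and was not turned for the dye swap. It was matched by normexp background correction with an offset of 30 and loess, which the labels do not state. The authors name limma without a version. All 8 scanner files carry 1 slide and 1 scan, so no slide or scan batch could be formed. All per-sample columns of the value table were assigned to a sample.

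The labels conflict on the dyes. The general labelling text gives Cy5 to trained and Cy3 to untrained RNA, while the channel labels of each sample alternate, and the latter were used. They coincide with the column of the array on the slide: odd columns hold trained RNA in Cy3. Each array was compared within itself, so that the ratio is the pair and no further pairing between the orientation groups exists.

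Values were read and fitted in R 4.3.3 with limma 3.58.1. Mean spot signals were background-corrected by normexp with an offset of 50 and normalised by loess within each array, with control spots at weight 0. Spots with an outlier flag were set to missing, and spots with 1 sequence were averaged. The 61657 spots other than controls have 50354 distinct sequences of 60 bases and 26091 targets. A probe was kept where at least 1 channel was well above background on at least 4 arrays. The log2 ratio was fitted with an intercept for dye bias and a training term coded by the dye of the trained RNA, followed by empirical Bayes moderation and Benjamini-Hochberg adjustment over the 36242 probes, with a threshold of 0.05. Such tests were two-sided. Gene lists were tested with camera at a preset correlation of 0.01 where at least 3 targets were kept, with an estimated correlation and fry beside it, on the mean of the probes of a target. Simulated data with the same design and probes recovered 37.3% of the changes put in at 1.2-fold, 86.6% at 1.5-fold and 98.5% at 2-fold, with 8 false calls. The median fitted log2 change was 0.22, 0.49 and 0.82 where 0.26, 0.58 and 1 were put in, so fold changes came out low. Simulated noise was independent between probes, whereas probes on the real arrays vary together, so the count of false calls need not carry over to them.

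Names of targets come from 2 sources. The files describe 639 targets by the best likeness to another organism, and the reference table held 2 targets. As these are few, each probe was translated and compared with 74 conserved proteins and Aplysia peptides entered from general knowledge after the files had been seen. A probe that encodes at least 12 identical residues was given the name, which applied to 72 probes of 45 targets on the printed strand, 42 probes on the other strand and 0 reversed sequences. Such a name is a family and not a proven ortholog. This was done in Python 3.11.15 with pandas 2.3.3 and Biopython 1.88, and figures were drawn with matplotlib 3.10.9.

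The rule for named genes was fixed before the data were examined, as were the lists, tests and most alternatives. It takes up to 25 probes past the threshold with the largest change the same way on all 8 arrays, 1 per target, the members of each list with the smallest p, the checks of tissue make-up and the 4 probes of largest dye effect. Targets with no name are given here by count, except for the largest rise and the 2 largest falls among probes that moved the same way on all 8 arrays. Chosen after seeing the data were the protein families, the described genes, scaling to the 10 spike-in probes, a correction for GC share, a fit without probes that carry a repeat of G and A, and a fit with an offset of 30. The alternatives fixed before the data were examined were no background correction, an offset of 16, the Agilent processed signals, median centring, scaling and quantiles of intensity between arrays, no filter and a stricter filter, outlier spots kept, no intercept, the row on the slide as a term, trained RNA read as Cy5 on all arrays, trend and robust priors, array weights, means per target, the deposited value table, other thresholds and each array left out in turn. Other splits of the 8 arrays into 4 and 4 (35 in all) were fitted in the same way. Single values were tested by exact permutation over these splits, two-sided, for which the smallest possible p is 0.0286.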

Results

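The arrays compared RNA of the pleural ganglia of the sea slug Aplysia californica between a trained and an untrained side, 7 days after training for long-term sensitization, a lasting rise of defensive reflexes after noxious stimulation. Per the labels, training gave 4 rounds of shock to 1 side of the body at intervals of 30 min, each with 10 pulses of 500 ms at 1 Hz and 90 mA. Each of the 8 arrays set pooled RNA of the trained sides of 2 animals against RNA of their untrained sides in the other dye, so that 16 animals were used, and the animals of a pool had been trained on opposite sides. Trained RNA carried Cy3 on 4 arrays (replicates 1, 3, 5 and 7) and Cy5 on 4 arrays (replicates 2, 4, 6 and 8). Among the spots other than controls, 63.3% to 67.3% were well above background in Cy3 and 69.1% to 73.0% in Cy5, and 0 were saturated. The filter on dim probes left 36242 probes, which stand for 20184 targets, as the printed transcript sequences are called here. The number of arrays limits the precision, with a median SE of the log2 fold change of 0.05.

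The main comparison asks which transcripts differed between the sides at a time when, per the labels, recall of the sensitization had decayed but savings could still be evoked. The precursor of FMRFamide, a neuropeptide that inhibits transmission from the sensory neurons of Aplysia, was higher on the trained side in both of its probes (M11283.1). The first gave a log2 fold change of 0.82 (SE 0.11, n = 8 arrays, limma adjusted p = 0.0065, 1.77-fold) and the second 0.83 (SE 0.11, limma adjusted p = 0.0069, 1.78-fold), each higher on 8 of 8 arrays. Its probes had a mean log2 intensity of 17.24 and 17.23. A transcript described as neurofascin, an adhesion molecule of neuronal membranes, rose by 0.31 (SE 0.05, limma adjusted p = 0.0117, 8 of 8 arrays). EB194357.1, which the files do not name, had the highest rise among probes past the threshold, 0.96 (SE 0.14, limma adjusted p = 0.0079, 1.94-fold, 8 of 8 arrays). Among decreases seen on all 8 arrays, EB241109.1 fell by 0.56 (SE 0.09, limma adjusted p = 0.0092) and EZ114792.1 fell by 0.51 (SE 0.08, limma adjusted p = 0.0079), the largest of these. The neurofascin target and both decreases lie outside the rule for named genes and were chosen after their values were seen. The calls of these targets lasted without each array in turn. They ended with trained RNA read as Cy5 on all 8 arrays, as the general labelling text can be read. Under that reading the fitted value is the intercept for dye bias of the main fit, and training cannot be told apart from dye. The loss of a call under it therefore does not test the training effect. FMRFamide then gave 0.41 and 0.38, neurofascin 0.0088 and EZ114792.1 -0.28, while EB194357.1 turned to -0.20 and EB241109.1 to 0.29. The call of neurofascin also ended with scaling to the spike-in RNA (0.14, limma adjusted p = 0.132). Neurofascin gave 0.69 with Agilent processed signals (limma adjusted p = 0.0309), 0.45 with no background correction (limma adjusted p = 0.0080) and 0.23 with GC correction (limma adjusted p = 0.0214). Its probe had a mean log2 intensity of 7.06 and a GC share of 0.517, in the range where 75 probes were called higher and 7 lower.

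**Figure D1:**
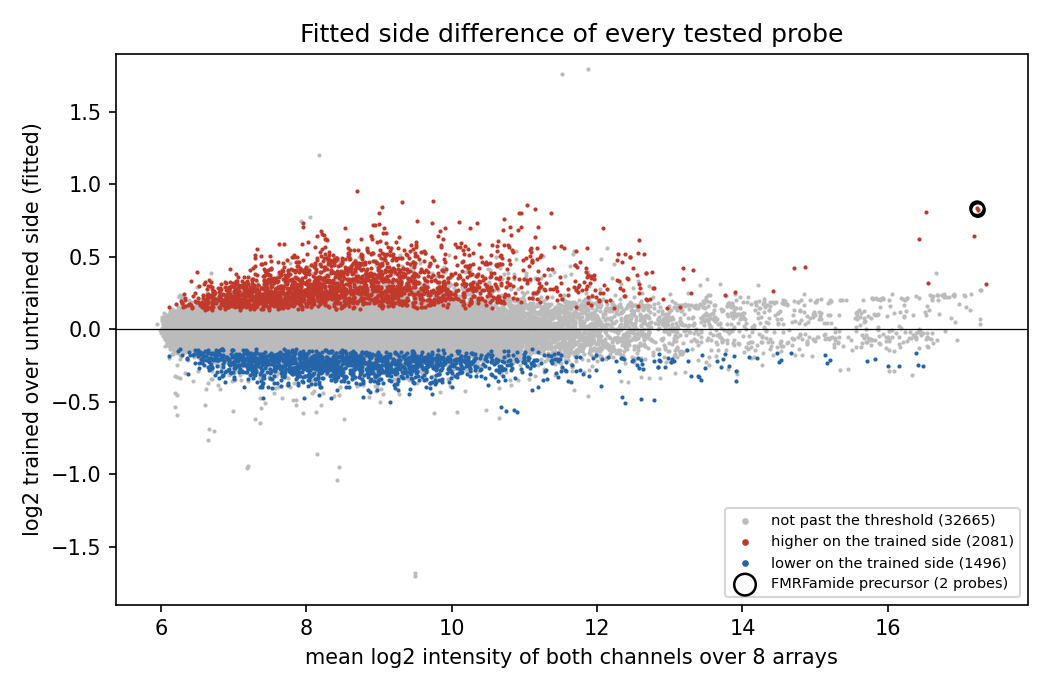
Each point is 1 of the 36242 tested probes, with the mean log2 intensity of both channels over 8 arrays on the x axis and the fitted log2 ratio of the trained over the untrained side on the y axis. Red points (2081) passed the threshold as higher and blue points (1496) as lower on the trained side, and the circle marks both FMRFamide probes, at 0.82 and 0.83.

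Of the probes recognised by sequence, 2 of 6 for protein kinases and phosphatases, 1 of 5 for heterotrimeric G proteins and 1 of 8 for chaperones passed, all as higher. None passed for tubulins (0 of 19), small GTPases (0 of 7), ubiquitin and proteasome (0 of 6), histones (0 of 4), translation (0 of 4) or actin (0 of 3). Over all tested probes 3577 of 36242 passed, so these few calls are not read as an excess in any family. The catalytic subunit of protein phosphatase 2A, which takes phosphate off serine and threonine residues, rose in both probes of FF077901.1, by 0.25 (SE 0.05, limma adjusted p = 0.0233, 8 of 8 arrays) and 0.23 (SE 0.05, limma adjusted p = 0.0285, 7 of 8 arrays). A target matched to a G protein alpha subunit of the Go class (DQ656111.1), a transducer between membrane receptors and ion channels, rose by 0.30 (SE 0.07, limma adjusted p = 0.0294, 7 of 8 arrays). Such a match may not tell related proteins apart, as the probes of a chaperone target were matched to both HSC70 and BiP. The chaperone HSP90 rose by 0.23 in the first probe of EB268546.1 (SE 0.04, limma adjusted p = 0.0150, 8 of 8 arrays). The second probe gave 0.14 (SE 0.05, limma adjusted p = 0.0985) and was higher only on the 4 arrays with trained RNA in Cy3. Its intercept for dye bias was -0.32 (limma adjusted p = 0.0057). Another HSP90 target gave 0.20 (SE 0.07, limma adjusted p = 0.112). Another target for protein phosphatase 2A gave 0.09 (SE 0.07), and the 3 probes of other targets matched to Go alpha gave 0.05 to 0.07, none past the threshold. These proteins were sought by sequence after the files had been seen. The HSP90 call ended without replicate 7 (0.22, adjusted p = 0.0557). That of protein phosphatase 2A ended without replicate 1, 6, 7 or 8 (0.21 to 0.25 in both probes, adjusted p 0.0588 to 0.0856) and in its second probe also without replicate 3 (0.22, adjusted p = 0.0583). That of Go alpha ended without replicate 1, 5, 6, 7 or 8 (0.24 to 0.31, adjusted p 0.0541 to 0.0795). All 3 calls ended with Agilent processed signals (0.24 to 0.40) and with scaling to the spike-in RNA (0.07 to 0.13). Median centring ended those of HSP90, the second phosphatase probe and Go alpha (0.16, 0.18 and 0.27), and leaving out the intercept ended those of HSP90 and Go alpha. With trained RNA read as Cy5 throughout all of these calls ended: HSP90 and the second phosphatase probe turned (-0.16 and -0.05), the first phosphatase probe gave 0.0064 and Go alpha 0.19.

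**Figure D2:**
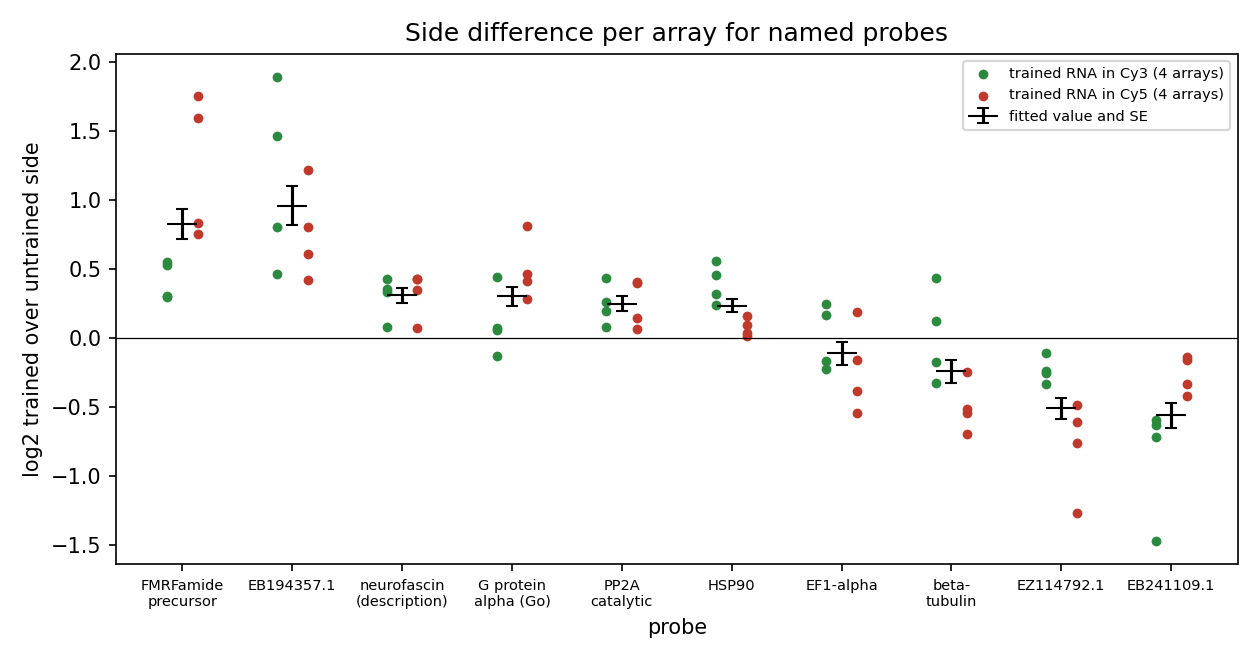
Log2 ratio of the trained over the untrained side for 10 probes, with a point for each of the 8 arrays, coloured by the dye of the trained RNA, and a bar for the fitted value with its SE. The FMRFamide precursor lay above 0 on 8 of 8 arrays (fitted 0.82), EZ114792.1 and EB241109.1 lay below 0 on 8 of 8 (fitted -0.51 and -0.56), and elongation factor 1-alpha and beta-tubulin did not pass the threshold.

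In all, 3577 of 36242 probes passed an adjusted p of 0.05 in limma, 2081 higher and 1496 lower on the trained side, with 9745 at an unadjusted p under 0.05. The fitted changes were small, though in the simulation they came out lower than put in. The median was 1.21-fold among increases and 1.18-fold among decreases, 70 probes rose by at least 1.5-fold and 0 fell by as much. On all 8 arrays, 1368 probes were higher and 917 were lower, where chance gives 142 each way. The probes past the threshold belong to 2491 targets, 1392 with an increase, 1099 with a decrease and 0 with both. Across the 16024 targets with 2 tested probes the fold changes of both probes correlated at r = 0.88, where targets are not independent replicates. The 2 probes of a target can overlap in sequence, and in the 4847 targets with 2 probes that do not overlap r was 0.82. The 25 probes of largest change that moved the same way on all 8 arrays, 1 per target, were all increases, from 0.65 to 0.96. They had limma adjusted p values of up to 0.0277, and of the 22 with a second tested probe 20 had it called the same way. FMRFamide was the single member of these 25 that could be named, and 2 of the 25 carry the repeat of G and A described under the other observations, which 0 of the 28 named probes carry.

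The number of calls depends on the arrays and on what is held constant. It was 1737 without replicate 1, 2209 without replicate 5, 1033 without replicate 6, 847 without replicate 7 and 1779 without replicate 8, while the direction of the majority stayed. Spike-in RNA was 0.17 higher in the trained channel (log2), so that scaling to it moved the median of all probes to -0.17 and gave 13318 calls, 425 higher and 12893 lower. All other values here are relative to the bulk of transcripts on the same array. GC-rich probes were higher on the trained side: the median GC share was 43.3% among increases, 38.3% among decreases and 40.0% among all tested probes.

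Of the 20 gene lists fixed in advance, 7 matched a description, since the files describe 639 of the 26091 targets, mostly by their likeness to proteins of other organisms. Oxidative phosphorylation, the sole list with enough measured members for a test, had 7 of its 12 matched targets above the filter and a median log2 fold change of 0.03 (camera p = 0.792, and p = 0.808 with an estimated correlation). Over all genes 0 of its members passed, and adjusted over the list alone 1 did, NADH dehydrogenase subunit 4, part of respiratory complex I, with -0.15 (SE 0.04, limma adjusted p = 0.0535 over all genes and 0.0391 over the list, lower on 7 of 8 arrays). Another target described as NADH dehydrogenase subunit 4 gave -0.01 (SE 0.06, limma adjusted p = 0.921 over all genes), so the fall was seen in 1 target and not in the other. ATP synthase F0 subunit 8 gave 0.10 (SE 0.05), and a target described by its likeness to NADH dehydrogenase subunit F of a plant gave 0.13 (SE 0.10). Over all genes, the first subunit 4 target passed as lower without replicate 4 (-0.17, adjusted p = 0.0449) and in 6 other alternatives. It gave -0.15 with no filter, no GA repeat or means per target and -0.17 with GC correction. It gave -0.22 with median centring (adjusted p = 0.0400) and -0.31 with scaling to the spike-in RNA (adjusted p = 0.0104). The ATP synthase value turned to -0.07 with scaling to the spike-in RNA. By limma's fry, whose adjusted p over this single list equals the raw one, oxidative phosphorylation had a limma adjusted p of 0.816 for a shift in 1 direction and 0.0568 for changes in either direction.

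The lists too small for a test held few measured members, of which 0 passed over all genes and 2 passed adjusted over the list alone. In heat shock and oxidative stress, Hsp70 gave 0.14 (SE 0.04, limma adjusted p = 0.0605 over all genes and 0.0140 over the list of 2). HSPC163, which matched by the first letters of its name and need not be a heat shock protein, gave 0.01. The Hsp70 probe was dim, with a mean log2 intensity of 6.30 (percentile 10.9 of the tested probes). Probes recognised by sequence as the chaperone HSC70 gave -0.0072, 0.046 and 0.11, none past the threshold. Over all genes, Hsp70 passed without replicate 1 (0.18, adjusted p = 0.0452), with an offset of 16 (0.27, adjusted p = 0.0363) or 30 (0.20, adjusted p = 0.0464). It also passed, at 0.14 to 0.15, with array weights, GC correction or means per target. Agilent processed signals gave Hsp70 0.37 (adjusted p = 0.150), and the value turned to -0.02 with scaling to the spike-in RNA. Mitochondrial ribosomal protein L21 gave -0.17 (SE 0.06, limma adjusted p = 0.0777 over all genes and 0.0110 as the single member of its list), and passed over all genes with GC correction (-0.24) and scaling to the spike-in RNA (-0.34). Of the cytoskeleton list profilin gave -0.01. A midasin-like target, which matched by a word of its description and need not be a cytoskeletal protein, gave 0.01. Cell adhesion matched 2 targets, and the markers of muscle and sheath and those of haemocytes matched 1 each, with 0 above the filter. The other 13 lists matched 0 descriptions, among them the genes linked to sensitization before this series, the neuropeptides, the sensory neuron marker sensorin and the markers of glia, so that the tissue make-up of both sides could not be compared by description.

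Of the tested targets with a description 23 of 342 passed, against 3577 of 36242 among all probes. The calls went both ways, and that of smallest p was a decrease of 0.35 in an unnamed protein product (limma adjusted p = 0.0093). A target described as phosphorylase phosphatase was 0.28 higher on the trained side (SE 0.07, limma adjusted p = 0.0320, 7 of 8 arrays). Sterolin-2, a sterol transporter, rose by 0.22 (SE 0.06, limma adjusted p = 0.0367, 7 of 8 arrays). BAI1-associated protein 1, a scaffold of cell junctions, rose by 0.18 (SE 0.05, limma adjusted p = 0.0480, 7 of 8 arrays). A target described as BCL9-like, a cofactor of Wnt signalling, fell by 0.20 (SE 0.05, limma adjusted p = 0.0323, lower on 8 of 8 arrays). The 4 named genes were chosen from the described targets after their values were seen. Each of their 4 calls ended without replicate 1, 2, 5, 6, 7 or 8, with values of 0.14 to 0.29 for the increases and -0.16 to -0.22 for the decrease, at adjusted p from 0.0545 to 0.132. All 4 also ended with Agilent processed signals and median centring (0.14 to 0.29, and -0.35 and -0.24 for BCL9-like). With scaling to the spike-in RNA the increases ended, at 0.11, 0.05 and 0.014 in the order given, while BCL9-like stayed past the threshold (-0.37). GC correction ended sterolin-2 (0.20, adjusted p = 0.0563) and BAI1-associated protein 1 (0.15, adjusted p = 0.0866). Leaving out the intercept ended the 3 increases, an offset of 16 ended sterolin-2 and BAI1-associated protein 1, and array weights ended sterolin-2. The call of BAI1-associated protein 1 also ended with no background correction, no filter, the row on the slide as a term, the deposited values and an offset of 30. Trained RNA read as Cy5 throughout ended all 4 calls. Phosphorylase phosphatase then gave 0.096, sterolin-2 0.12 and BCL9-like -0.0061, and BAI1-associated protein 1 turned to -0.079.

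Protein families recognised by sequence showed no shift that passed with a preset or an estimated correlation. Tubulins, the building blocks of microtubules, had a median of -0.07 over 10 targets, 7 of them below 0, with 0 of 19 probes past the threshold (camera adjusted p = 0.153, and adjusted p = 0.490 with an estimated correlation). An alpha-tubulin (FF067252.1) gave -0.17 (SE 0.05, limma adjusted p = 0.0582) and a beta-tubulin (FF072817.1) gave -0.24 (SE 0.08, limma adjusted p = 0.0817). Both passed without replicate 3 (-0.20 and -0.31, adjusted p = 0.0380 and 0.0281) and with scaling to the spike-in RNA (-0.34 and -0.41). The first also passed with GC correction (-0.20) and with trend and robust priors (-0.17), the second with median centring (-0.33). Chaperones had a median of 0.11 over 5 targets, heterotrimeric G proteins 0.14 over 4, protein kinases and phosphatases 0.08 over 5, small GTPases 0.08 over 4, ubiquitin and proteasome genes 0.00 over 4 and translation factors with ribosomal protein L11 -0.07 over 3. Their camera adjusted p values ran from 0.136 to 0.736, and fry, which does not compare a family with other genes, gave 0.0481 for chaperones and for translation. Scaling to the spike-in RNA moves each of these medians below 0 with the bulk of probes.

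Widely expressed genes often taken as references stayed within the threshold. Actin gave 0.06 to 0.11 in 3 probes, GAPDH gave 0.08 and 0.09, calmodulin 0.04, a 14-3-3 protein -0.01 and elongation factor 1-alpha -0.09 and -0.11 (SE 0.07 and 0.08). Histone H4 gave 0.22 (SE 0.10, limma adjusted p = 0.177), and VCP, an ATPase of protein degradation, gave 0.13 (SE 0.04, limma adjusted p = 0.0858, higher on 8 of 8 arrays). With scaling to the spike-in RNA elongation factor 1-alpha passed as lower (-0.28, adjusted p = 0.0359) and the first VCP probe turned to -0.03, so a direction for these genes holds relative to the bulk of transcripts.

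The dye comparison asks how large the shift is that the balanced swap removes. An intercept past the threshold was found for 2545 probes, 1494 brighter in Cy5 and 1051 brighter in Cy3, and the median absolute dye coefficient was 0.06 against 0.07 for training. The largest coefficient past the threshold was -1.12 (limma adjusted p = 3.7e-06), for a probe with -0.02 for training. The largest coefficients of all, -1.78 and -1.71 for both probes of 1 target, did not pass, and the log2 side ratio of this target ran from -9.12 on replicate 2 to 2.26 on replicate 5. Of the FMRFamide probes, the first had a dye coefficient of 0.41 (limma adjusted p = 0.0483) and the second 0.38 (limma adjusted p = 0.0737). These are the values given above with trained RNA read as Cy5 throughout. Median centring in place of loess gave 29820 probes with a dye effect.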

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

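The splits of the arrays, the slide column, the channel labels and the spike-in permutation and probe tests were chosen after the results were seen. The GC correction and the median centring of the spike-ins were also added later, with the outcome of each unseen when its test was set.

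In 4 of the 68 groups of 4 arrays tested, 1 array stood apart from the other three, where chance gives about 1 in 20 groups. EB241109.1 was at -1.47 on replicate 1 against -0.72 to -0.60 on the other arrays with trained RNA in Cy3. Sterolin-2 was at -0.15 on replicate 3 against 0.16 to 0.19. Mitochondrial ribosomal protein L21 was at -0.37 on replicate 5 against 0.0036 to 0.06. Hsp70 was at 0.082 on replicate 1 against 0.30 to 0.34.

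Of the 35 splits of the 8 arrays into 4 and 4, only the real one (1 split) gave as many as the 3577 calls between the sides. The highest of the others gave 0 calls in limma, with up to 5998 probes at an unadjusted p under 0.05 against 9745 in the real split. This argues against a random grouping of the arrays as the source of the count but does not exclude it. The 35 splits allow no exact permutation p below 0.0286, and in the others the real difference adds to the residual spread. A gradient of the dye ratio along the columns of the slide was sought in the split of columns 1 and 2 against 3 and 4. It gave 0 calls, with 323 probes at an unadjusted p under 0.05. Every split but the real one gave 0 calls, and in each the real difference adds to the residual spread. This split therefore cannot decide on a gradient. Whether trained RNA was labelled with Cy5 on all 8 arrays and the channel labels are wrong cannot be told apart from the labelled swap, since the split by the channel labels (3577 calls) is also that of odd against even columns. A base composition trend is argued against as the whole cause, since 2996 of the same calls remained after the GC trend was taken off each array. A difference that follows training stays open as a hypothesis, as do a difference between odd and even columns and a gradient along the columns.

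Spike-in RNA, which was not part of the main measurement, was 0.17 higher (log2, SE 0.05, 1.12-fold) in the trained than in the untrained channel, with the dye difference taken off. Random differences of single labelling reactions are argued against by an exact permutation p of 0.0286, the smallest that the 35 splits allow, though the largest other split reached 0.15 and the shift was 0.12 without replicate 1, whose own value was 0.47. Leaving out replicate 2, 4, 6 or 8 gave 0.15 to 0.18 with an exact permutation p of 0.0571. The loess curve at the intensity of these probes may account for part of the shift, as median centring gave 0.12 (SE 0.05, exact permutation p = 0.0857) and the Agilent processed signals gave 0.19. Less labelled RNA of the ganglia per ng of total RNA on the trained side remains open, since 0 of the 10 spike-in probes had a shift of opposite sign (0.11 to 0.22) but the RNA input of each reaction is known only as a nominal 300 ng.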

How the results depend on the processing

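The fits with spike-in scaling, GC correction, an offset of 30 and no probes with a GA repeat, and the alternatives for families, spike-ins and the GC slope, were chosen after seeing the data. The count of 3577 calls kept within 1.5 times, from 3252 to 4157, under no background correction, offset 16, scale normalisation, both other filters, outliers kept, the row term, trend and robust priors, array weights, the deposited values, offset 30, GC correction and no GA repeat, and increases outnumbered decreases in each. Quantiles of intensity between arrays leave the ratios as they were. It was 1884 with Agilent processed signals, 2041 with median centring, 2025 with no intercept, 1365 with trained RNA read as Cy5 throughout (16 of the same probes), 13318 with spike-in scaling (1918 of the same probes), 2144 with means per target (fewer tests), 6269 at an adjusted p of 0.10 and 70 with at least 1.5-fold, and from 847 to 4142 with 1 array left out. The dye count was 29820 with median centring, since loess removes dye curves, and 2382 to 2871 otherwise. The median of oxidative phosphorylation turned to -0.0043 with no filter, was 0.089 with Agilent processed signals and was 0.0051 to 0.05 with 1 array left out. With trained RNA read as Cy5 throughout, the fitted value is the dye intercept of the main fit, so it does not test training. In that fit values turned for EB194357.1 (-0.20), EB241109.1 (0.29), the second phosphatase 2A probe (-0.048), HSP90 (-0.16, -0.32 and -0.070), BAI1-associated protein 1 (-0.079) and Hsp70 (-0.12). With spike-in scaling they turned for the second HSP90 probe (-0.031), ATP synthase F0 subunit 8 (-0.067), Hsp70 (-0.022) and VCP (-0.033). The probe of largest dye effect (-0.02) gave 0.029 with processed signals, 0.0097 with median centring, 0.0023 with scale normalisation and 0.00024 with array weights. For the 28 named probes 654 alternatives kept direction and side of the threshold, 86 lost the call, 27 gained one and 16 turned. Apart from the constructions named, the cause was not tested. Slide or scan as a block was not run, since all arrays share 1 slide and 1 scan. Per channel and array, 63.3% to 73.0% of spots were well above background, and the count was 3252 with no filter and 3629 with the strictest one.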

Other observations

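Tests on protein families were chosen after the values of their probes had been seen, and the group of probes that vary together was found in the data, with both of its tests set before their outcome was seen.

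Some targets differed between the sides by far more on single arrays than on others, and those given here did not pass the threshold for training. The 2 probes of 1 target had log2 ratios of the trained over the untrained side of -9.03 and -9.12 on replicate 2 and of 2.26 and 2.21 on replicate 5. Both probes of another target gave 5.50 and 5.80 on replicate 7 and -2.80 and -3.09 on replicate 8, and within 0.60 of 0 on the other 6 arrays. The largest fitted increase that did not pass was 1.79 (SE 0.54, limma adjusted p = 0.0642), higher on 6 of 8 arrays, with a ratio of 4.61 on replicate 7 and -0.43 on replicate 4.

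Bright probes whose log ratios vary together over the arrays form a group of 210 probes for 186 targets, out of 262 tested probes with an SD of at least 1. Their mean side ratio ran from -1.46 on replicate 8 to 1.77 on replicate 5, and 0 of them passed for training (lowest limma adjusted p = 0.365). A GA repeat of at least 6 bases stands in 199 of the 210 (94.8%) against 1494 of the 36242 tested probes (4.12%). Transcripts of the targets that differ in amount between the channels are argued against, since 2 of 76 second probes without the repeat, for the same targets, correlated with the mean of the group at 0.9 or more. A GA repeat in the probe that binds labelled nucleic acid other than the target is a candidate explanation, with a median slope of those second probes on the group mean of 0.0098 (SE 0.02), where 1 would mean that they follow it. A fit without probes that carry the repeat gave 3870 calls and kept 3472 of the 3577. The other 105 calls carry the repeat and were left out of that fit, so its count does not bear on this explanation.

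GC share and fold change were related across probes, which are not independent replicates. The slope of the log2 fold change was 0.60 per unit of GC share (Spearman rho = 0.20), positive on 7 of 8 arrays, from -0.38 on replicate 2 to 1.24 on replicate 7. Of the 35 splits only the real one gave a slope as large (exact permutation p = 0.0286, the smallest possible), with 0.56 in the largest other split. In 4847 targets with 2 probes that do not overlap, the slope was 0.05 (SE 0.03) between probes of 1 target and 0.91 (SE 0.05) between targets. Of the 7999 probes with a GC share of 35% or less 239 were called higher and 433 lower, of the 12669 with 43.3% to 45% 1049 and 380, and of the 754 with 46.7% or more 75 and 7.

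The hypothesis that members of a family move together between the sides was tested on the protein families found by sequence. With both correlations 0 of 7 families had an adjusted p under 0.05, and 2 had one in fry, so the test leaves it open.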
